A study of Mus musculus with 8 samples.

How the data were processed

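RNA crosslinked to Ptbp2 was sequenced from the cortex of wild-type CD1 mouse embryos at embryonic day 18.5, with 4 libraries from each of 2 brains. HITS-CLIP crosslinks a protein to the RNA it touches with ultraviolet light, recovers the complexes with an antibody and sequences the bound fragments. No library of another genotype, antibody or input RNA was analysed here, so tag density reflects both binding and transcript abundance.

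The deposited data were one list of mapped tags, 1 row per tag, with chromosome, start, end, strand and a tag name that opens with a library code. The 8 codes matched the 8 sample titles, and 0 tags were left without a library. The deposited score column held the value 0 in each row and was not used as a measurement. The submitters' processing notes name Bowtie, without a version, and the builds mm8 and mm9. Tags on chromosome 1 ran to position 197194446, which lies past the published end of that chromosome in mm8 and within mm9, so coordinates are given as mm9, counted from 1. Per the labels' protocols each read opened with 4 degenerate bases and a G; whether and how repeated reads were collapsed, and how multiply mapping reads were treated, is not given in the sources used here. Because the gene table at hand describes another assembly, GRCm38.p6, no gene names were assigned and sites are named by position. Tag shares by annotated region, gene lists, hexamer enrichment and cassette exons were planned and are not analysed here.

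Tags of all libraries were pooled and joined into clusters where they overlapped by 1 nt or more on one strand, and the height of a cluster is its largest number of tags over one base. Clusters of height 10 or more were the main set. Tags were also counted in strand-specific windows of 10 kb by tag midpoint. Tags of each library were counted per cluster and window from the deposited rows. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Single values per library were compared between brains with two-sided exact permutation tests, for which 4 against 4 libraries cannot give a p below 0.0286.

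The comparison between brains was planned as a quasi-likelihood test on counts per gene. Because the deposited file is a tag list, not a count table, and no annotation of its build was used, limma 3.58.1 (voom, in R 4.3.3) was applied to clusters and windows instead. Voom was chosen before the brains were compared, and the use of clusters and windows as units after the file was seen and after an exploratory chi-square comparison of both. Features needed at least the CPM that 10 tags make in a library of median depth in 4 or more libraries, and 15 tags in all. The alternative without this count filter still took only the 22803 clusters of height 10 or more and the 34816 windows with 20 or more tags. Libraries were scaled by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed at each end), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The 4 libraries of a brain share one animal, so these p-values measure only the spread between libraries, which is technical. The titles also carry a letter, a for libraries 1 and 2 of a brain and b for libraries 3 and 4, whose meaning the labels do not give. Libraries 1 and 2 were the most alike pair of each brain (chi-square per degree of freedom over windows 1.13 and 1.16) and libraries 3 and 4 were not (1.25 and 1.51). Libraries of a letter may therefore not be independent, and p-values that treat them so may be too small. Tested on simulated data for 466 clusters with 200 changed, the same test recovered 76.0% of 2-fold and 100% of 4-fold increases in brain 2, and 56.0% of decreases to 0.5 and 96.0% of decreases to 0.25 (50 clusters each), and called 2 of 266 unchanged clusters. For 3756 windows with 200 changed it recovered 56.0% of 2-fold increases, 16.0% of decreases to 0.5 and 82.0% of decreases to 0.25, and called 3 of 3556 unchanged windows. Changing 200 features makes the adjusted threshold easier to pass than in the data, where 6 clusters and 45 windows passed. Power on the data is therefore probably lower. The simulation also gave all features of a unit 1 dispersion and treated libraries as independent.

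The sites named were fixed by rule before the data were examined: the 20 tallest clusters, and up to 5 features with the largest change each way past the threshold whose direction held in each pair of libraries. The text gives the tallest few in full. Alternatives fixed beforehand were another scaling, no filter, the replicate number as a block, each library left out, repeated rows counted once, other cluster heights and a 10-nt overlap. Added after the data were seen were scaling by total tags, a quasi-Poisson F test on variances moderated with limma, leaving out clusters with a position of 64 or more tags in a library, clusters called in each brain alone, the letter as a random block or with its 2 libraries summed, other neighbour distances and, for the sharing, height and strand of clusters only, repeated rows counted once per library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for counting, intervals and plots.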

Results

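Ptbp2, the polypyrimidine tract binding protein enriched in neurons and a regulator of alternative splicing, was crosslinked to RNA in the embryonic mouse cortex, and the bound fragments were sequenced to find where it contacts transcripts. The 8 libraries fell into 4 from each of 2 brains and held 3098854 mapped tags. Brain 1 was the deeper, with 1932995 tags against 1165859 in brain 2. Single libraries held between 228424 tags (brain 2, library 4) and 545387 tags (brain 1, library 1). Tags were 27 to 30 nt long, and 43.1% had the full 30 nt. Positions are mm9 and carry no gene annotation.

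A small share of the tags lay in tall clusters, and many tags lay alone. Without input RNA or another antibody, tall clusters cannot be told from abundant transcripts, nor can single tags be taken as background. Ribosomal and other abundant non-coding RNA was to be set apart. This was not done, because no genes were assigned, so clusters named below may include it. Of 1680991 clusters of overlapping tags, 1184970 were a single tag, and these held 38.2% of the tags. Clusters of height 10 or more numbered 22803 and held 15.7% of the tags, with a median width of 42.0 nt. A height of 100 was reached by 220 clusters, of which 112 were no wider than 50 nt. The 20 tallest clusters held 0.888% of the tags, and 14 of them lay on the minus strand.

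The tallest cluster lay on chromosome 7 from 118219582 to 118219741 on the minus strand, with 6851 tags over its highest base. Scaled to library depth (CPM, tags as a rate of the library's total), it held 2060 ± 84.9 CPM in brain 1 and 3011 ± 670 in brain 2 (SD, n = 4 libraries each). Chromosome 17 held 4 of the 20 on the plus strand within a short stretch, the largest from 39983296 to 39983653 with a height of 4545. That cluster held 1691 ± 168 CPM in brain 1 and 2489 ± 425 in brain 2 (SD, n = 4). Its neighbours ran from 39983820 to 39983874 (height 1974), from 39984375 to 39984497 (height 1175) and from 39983971 to 39984027 (height 391). The third tallest lay on the minus strand of chromosome 16 from 18533282 to 18533424, with a height of 1980. The sixth lay on the plus strand of chromosome 6 from 47731659 to 47731724, and its 302 ± 16.9 CPM in brain 1 and 315 ± 34.4 in brain 2 (SD, n = 4) differed by less than the spread between libraries. Several of the others were narrow stacks. On the minus strand of chromosome 14, from 53092293 to 53092323, 87.3% of 417 tags shared one start and end, and on the minus strand of chromosome 6, from 26646313 to 26646345, 84.4% of 564 tags did. These heights count repeated positions: with each position counted once over all libraries, 0 clusters reached a height of 100, and with it counted once per library 14 did.

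**Figure D1:**
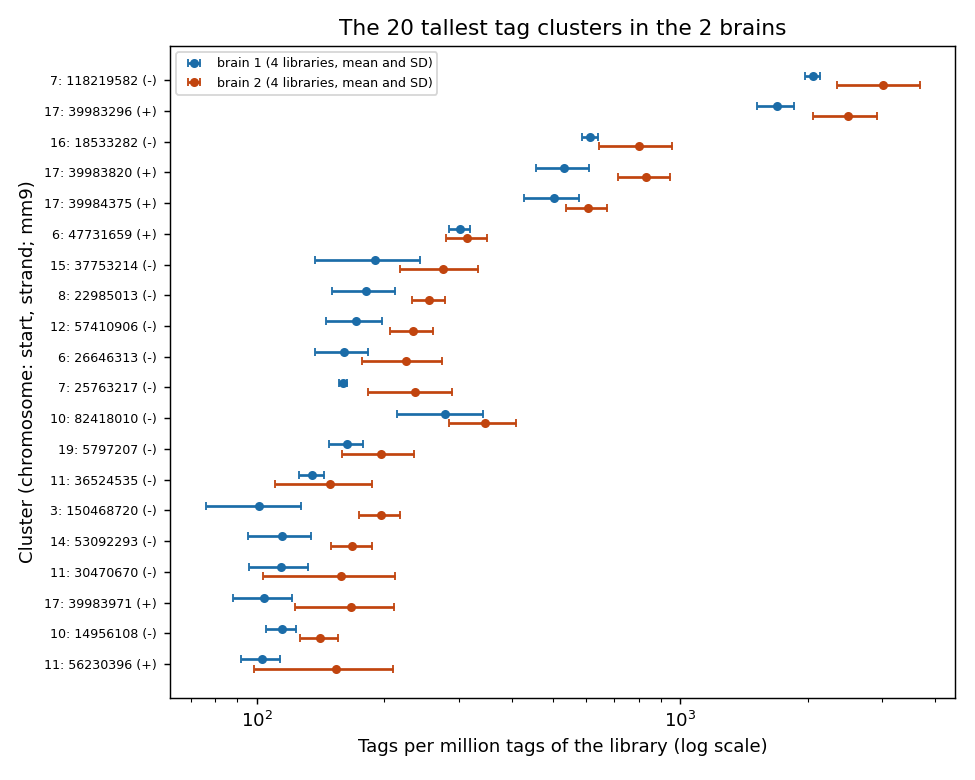
CPM (log scale) of the 20 tallest clusters, each named by chromosome, start and strand; points are means and bars SDs of 4 libraries per brain. The cluster on chromosome 7 sits highest, at 2060 in brain 1 and 3011 in brain 2.

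Clusters lay near one another on the same strand. Of 22695 clusters on the assembled nuclear chromosomes, 20.2% had another within 1000 nt on the same strand (95% interval 19.7 to 20.8%), against 0.189% on the opposite strand and 0.767% around points moved along the chromosome. Linking clusters separated by 20 kb or less on one strand gave 13804 groups, of which 183 held 10 or more clusters and together 16.6% of all clusters. The largest group, on the minus strand of chromosome 2 from 6461055 to 6900698, held 225 clusters and 6979 tags over 440 kb. Its clusters drew 2394 ± 189 CPM in brain 1 and 2036 ± 306 in brain 2 (SD, n = 4). The next were on the plus strand of chromosome 16 from 6809381 to 7201718 with 93 clusters, on the minus strand of chromosome 11 from 36386301 to 36694373 with 77, and on the minus strand of chromosome 6 from 77244300 to 77541943 with 73. The densest of the 12 largest was on the minus strand of chromosome 1 from 170286615 to 170356868, with 71 clusters in 70.3 kb. Among 40036 windows of 10 kb with 20 or more tags, the fuller strand held a median of 96.6% of the tags, where equal strands would give 55.6%.

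**Figure D2:**
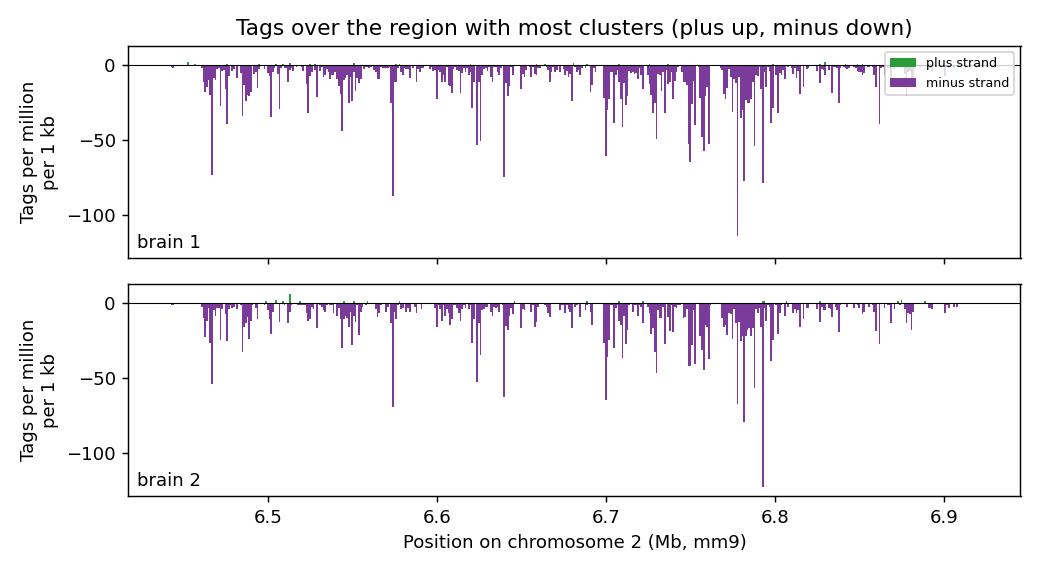
CPM per 1 kb over the minus strand group on chromosome 2 and 20 kb on each side, brain 1 above and brain 2 below, with plus strand tags drawn upward and minus strand tags downward. The 225 clusters between 6461055 and 6900698 lie on the minus strand in both brains.

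The 2 brains, which are biological replicates, were compared for the sites they share. Of the 22803 clusters of height 10 or more, 22597 (99.1%, 95% interval 98.97 to 99.22%) held tags of both. Random assignment of tags would give 99.7%, which lies above that interval. Tags of brain 1 alone made up 199 clusters and tags of brain 2 alone 7. All 8 libraries were present in 23.8% of clusters, where random assignment gives 33.5%. Pooling before clustering favours such sharing, so clusters were also called in each brain alone. Of 21063 clusters of height 5 or more in brain 2, 66.7% overlapped one called in brain 1 (95% interval 66.1 to 67.3%), against 0.461% after a shift of 50 kb. In the other direction, 33.0% of the 42612 clusters of brain 1 overlapped one of brain 2. With brain 1 thinned to the depth of brain 2 the shares were 46.1% and 51.5%. Tag ends recurred too: 171121 of 905961 distinct 5′ ends in brain 2 (18.9%) were also 5′ ends in brain 1, 4.80 times as many as at a shift of 1 nt.

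Among 466 clusters tested between the brains with limma voom, 6 passed an adjusted p of 0.05, 5 higher and 1 lower in brain 2. An unadjusted p under 0.05 was seen in 89, where chance gives 23.3. Other splits of the libraries gave up to 51, in a split that kept 3 libraries of each brain together. Splits with 2 libraries of each brain on each side gave up to 37. In 59 (12.7%) all libraries of one brain lay above all of the other, where chance gives 2.86%. The cluster with the largest change lay on the minus strand of chromosome 5 from 58424059 to 58424090, at 26.99 ± 9.98 scaled CPM in brain 1 and 79.2 ± 10.99 in brain 2 (SD, n = 4), a log2 change of 1.64 ± 0.26 (SE, adjusted p = 0.000365). On chromosome 3 the cluster from 150468720 to 150468760, minus strand, was higher by 0.80 ± 0.18 on the log2 scale (adjusted p = 0.0124), a call lost without library 1 of brain 1 (adjusted p = 0.0711) or library 2 of brain 2 (adjusted p = 0.0997). The tallest cluster, on chromosome 7, was higher by 0.34 ± 0.07, and 2 of those on chromosome 17 by 0.36 ± 0.08 and 0.46 ± 0.11. These sizes depended on the scaling, since total tags gave 0.52, 0.54 and 0.64, and the windows that hold them were higher by 0.71 ± 0.08 and 0.66 ± 0.08. With repeated positions counted once per library the changes were 0.24, 0.20 and 0.52 and no longer passed (adjusted p = 0.130, 0.218 and 0.0983). Without library 1 of brain 1 neither of the chromosome 17 clusters passed (adjusted p = 0.0574 and 0.144). The second of them also failed without library 2 of brain 2 (adjusted p = 0.0997) and with the replicate number as a block (adjusted p = 0.0641). In the quasi-Poisson F test the chromosome 7 cluster (adjusted p = 0.0566) and the first on chromosome 17 (adjusted p = 0.0549) did not pass. The cluster that was lower in brain 2, on the minus strand of chromosome 19 from 5797547 to 5798092, held 190 ± 30.2 scaled CPM in brain 1 and 108 ± 45.9 in brain 2 (SD, n = 4), a log2 change of -0.90 ± 0.21 (adjusted p = 0.0143). It no longer passed without library 1, 2 or 3 of brain 2 (adjusted p = 0.142, 0.0601 and 0.188) or with total scaling (adjusted p = 0.0763). Each of the 6 was on the same side in each pair of libraries. Scaling by total tags, which moved the median log2 change from 0.02 to 0.16, gave 15 clusters, all higher in brain 2. With repeated positions counted once per library, 72 clusters were tested and 4 passed, 2 each way, of which 1, that on chromosome 19, was among the 6. The chromosome 5 cluster, with 15 such tags in brain 1 and 18 in brain 2, was then below the filter. Leaving out clusters with a position of 64 or more tags in a library takes out 4 of the 6 themselves, those on chromosomes 3, 7 and 17; the chromosome 5 cluster then passed and that on chromosome 19 did not (adjusted p = 0.0528). Without library 1 of brain 1 there were 3, and with the 2 libraries that share a letter in their titles summed there were 3, those on chromosomes 3, 5 and 19.

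Windows of 10 kb can also take in scattered tags, but some held little beyond 1 cluster. Of 3756 tested, 45 passed, 44 of them higher in brain 2 and 39 on the same side in each pair of libraries. The window at 18530001 on chromosome 16, minus strand, passed (limma voom, adjusted p = 0.00413). Its 1183 and 910 tags are those of the third tallest cluster, which did not pass. Windows and clusters share tags and were scaled separately, so 45 and 6 calls cannot be compared directly. Total scaling gave 8 windows and 15 clusters. In simulated windows, with 200 of 3756 changed, the test recovered 56.0% of 2-fold increases in brain 2 and 16.0% of decreases to 0.5. The excess of increases may therefore partly follow from its power. Scaling may add to it, since log2 changes lay higher than under total tags, which gave 8 windows, all higher in brain 2. The filter could be met by 1 brain alone, and with fewer tags in the shallower brain 2. The window at 137740001 on chromosome 5 met it through brain 2 alone (10, 14, 18 and 11 tags), that at 42350001 on chromosome 1 through brain 1 alone. These sources were not told apart. An unadjusted p under 0.05 was seen in 388, where chance gives 187.8. Other splits of the libraries gave up to 341, in a split that kept 3 libraries of each brain together. Splits with 2 libraries of each brain on each side gave up to 271. The brains were fully separated in 255 (6.79%). The window from 42350001 to 42360000 on the plus strand of chromosome 1 held 84 tags in brain 1 and 2 in brain 2. Per unit of depth the pooled tags give a 25.3-fold excess in brain 1 (95% counting interval 6.80 to 213). In the limma voom test this window had a log2 change of -3.87 ± 0.97 (SE, adjusted p = 0.0334). It lost the call in 7 of 13 alternatives, among them without library 4 of brain 1 (adjusted p = 0.0871) and without library 1 or 2 of brain 2 (adjusted p = 0.0584 and 0.228), and it fell below the filter without library 1, 2 or 3 of brain 1. The 84 tags divided as 24, 19, 28 and 13 over the libraries of brain 1, and both tags of brain 2 came from library 3. The window just before it held 65 and 39 tags. The largest increase, by 2.05 ± 0.26 on the log2 scale (adjusted p = 5.33e-06), was in the window that holds the chromosome 5 cluster. That window held 48 and 100 tags and the cluster 48 and 99, so the window adds no separate result. Scaling by total tags gave log2 changes of 1.82 for the window and 1.80 for the cluster. Others among the largest began at 137740001 on chromosome 5, at 17610001 on chromosome 4, at 160450001 on chromosome 1 and at 36260001 on chromosome 2, with log2 changes of 1.60 ± 0.32, 1.53 ± 0.36, 1.40 ± 0.34 and 1.43 ± 0.38. The first of these lost the call in 3 of 15 alternatives. These were without library 1 of brain 1 (log2 change 1.54, adjusted p = 0.0698), without the count filter (1.43, adjusted p = 0.0756) and with total scaling (1.39, adjusted p = 0.0566). The last 3 lost it in most of their alternatives. In 22 of the 44 windows higher in brain 2, one position held over 25% of the tags, as it did in 10.97% of all windows tested. Scaling by total tags, which moved the median log2 change from -0.01 to -0.21, gave 8 windows, and leaving out library 1 of brain 1 gave 16, all of them among the 45. Counting repeated positions once per library, with 2345 windows tested, gave 14, of which 12 were among the 45. Without the count filter 13 passed, of which 11 were among the 45, but the 34816 windows then tested all held 20 or more tags. Summing libraries that share a letter gave 22, all among the 45.

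**Figure D3:**
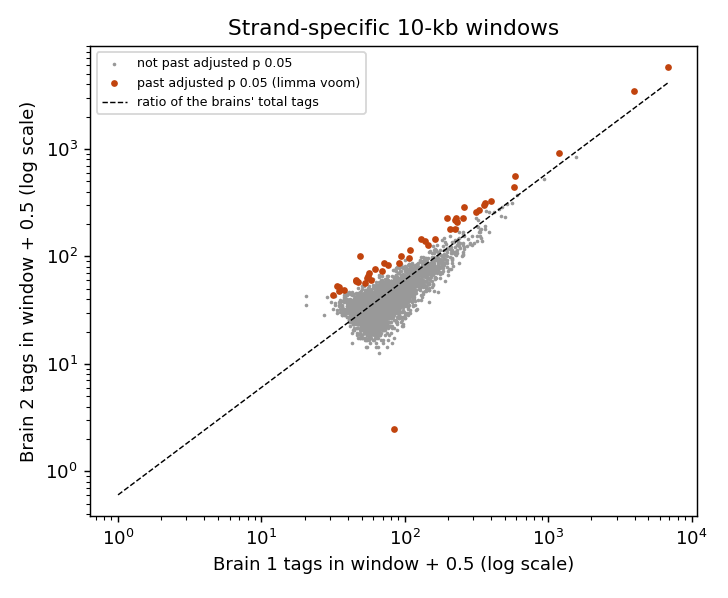
Brain 1 against brain 2 tags, plus 0.5, in the 3756 strand-specific 10-kb windows tested (both axes log), with the 45 windows past an adjusted p of 0.05 in red and the ratio of the brains' total tags as a dashed line. The window with 84 and 2 tags lies far below the line.

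Tags lay more often on the minus strand. The plus strand held 42.6% of all tags (95% interval 42.6 to 42.7%), 43.0 ± 0.47% in brain 1 and 42.1 ± 0.60% in brain 2 (SD, n = 4, exact permutation p = 0.0571). The plus strand share was under 50% on 19 of the 20 chromosomes other than Y, and reached 54.5% on chromosome 12 (95% interval 54.2 to 54.8%). It was lowest among those 20 on chromosome 1, at 36.7%. The mitochondrial chromosome, with 555 tags, had 98.0% on the plus strand. Clusters of height 10 or more per megabase were most frequent on chromosome 16, at 13.3, and least on the X chromosome, at 7.30. The share of tags on chromosome 16 was 4.72 ± 0.07% in brain 1 and 4.48 ± 0.08% in brain 2, and that on chromosome 17 was 3.93 ± 0.07% and 4.08 ± 0.09% (SD, n = 4, exact permutation p = 0.0286 for each, the smallest possible). With this floor an adjusted p under 0.05 over 21 chromosomes would need 13 of them at it, so the adjusted exact permutation p of 0.300 decides nothing for these 2.

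**Figure D4:**
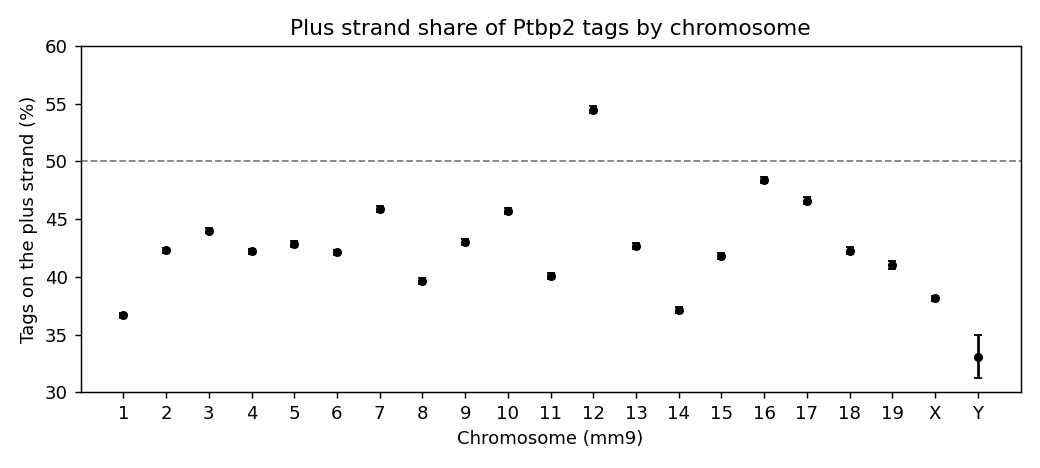
Share of tags on the plus strand for each of the 21 assembled nuclear chromosomes, all libraries pooled, with exact 95% intervals and a dashed line at 50%; the mitochondrial chromosome is not drawn. Of those drawn, chromosome 12 alone lies above the line, at 54.5%.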

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

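The tests of a few loci, of repeat removal and of transcript density on the strands were chosen after the result they bear on had been seen; the others were fixed beforehand. In 70 sets of 4 libraries of one brain, 5 had a library far from the other 3, where chance gives about 1 in 20. Library 1 of brain 1 was the deepest, with 545387 tags, and held 86.2 CPM of the chromosome 14 cluster that starts at 53092293. Library 4 of brain 2 gave the other 3. It held 4010 CPM of the tallest cluster on chromosome 7, 1003 of the chromosome 17 cluster that starts at 39983820 and 206 of the chromosome 11 cluster that starts at 36524535. That library was also the shallowest and had the largest share of repeated positions, 18.6%, against 8.09 to 12.8% in the others.

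Clusters with many tags held relatively more of them in brain 2: the median log2 ratio per total tags was 0.12 in clusters with 40 to 99 tags and 0.46 in those with 400 or more. With 4 degenerate bases a position can hold at most 256 distinct codes, and the fullest position held 168 to 209 tags in each library although depth ranged 2.39-fold, so a ceiling may flatten the deeper brain. Correcting each position for equally used codes still left an excess of 0.34 (bootstrap interval 0.14 to 0.41), and over thinly filled positions the median was lower by 0.16 than over all positions (value -0.16, interval -0.33 to 0.04). The excess hardly moved from its 0.34 before the correction, and its interval lies above the 0.1 expected if equally used codes were the whole cause, though it reaches below the 0.2 set to exclude a ceiling. Unevenly used codes were not tested, and the interval over thin positions spans both of its bounds, so a ceiling and more crosslinking in brain 2 both stay open.

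The excess of minus strand tags was not due to a few loci, since the plus share was 42.9% without the 1000 fullest windows. Repeated positions differed by 0.143 percentage points between the strands. That value covers only rows left in the deposited list and cannot show how many were removed from each strand before, so unequal repeat removal is not excluded. Tags on the emptier strand were 1.38 times as frequent where the plus strand led (bootstrap interval 1.25 to 1.501), which more or denser transcripts on the minus strand and a lower recovery of plus strand tags would both give. Thinning the minus strand at random to the plus strand's tags gave 0.965 times as many clusters of height 10 or more as the plus strand, consistent with a uniform lower recovery of plus strand tags. It was not under the 0.9 set for more or denser minus strand transcripts, a bound that more transcripts would have to meet but equally many, denser ones would not, since thinning them leaves about as many clusters as on the plus strand. More or denser minus strand transcripts and a lower recovery of plus strand tags both stay open. The range of plus shares from 36.7% on chromosome 1 to 54.5% on chromosome 12 does not separate them.

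Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many clusters (6, highest other 0), and 1, again the real one, called as many windows (45, highest other 1). At an unadjusted p under 0.05 the highest others were nearer, 51 clusters against 89 and 341 windows against 388. Both came from a split that keeps 3 libraries of each brain together, so part of the difference between brains remains in it. With 2 libraries of each brain on each side the highest were 37 clusters and 271 windows. If the 8 libraries are exchangeable, chance would make the real split the highest at 1 in 35 for each count, the smallest share that 35 splits can give. If libraries that share a letter in their titles are not independent, 3 splits keep the letters whole, too few for a share under 0.05 (6 clusters against 0 in both others, 45 windows against 0 in both others). Each library of brain 1 (458293 to 545387 tags) was deeper than each of brain 2 (228424 to 340852), so depth follows the real split too. With 1 animal on each side the real split separates animals, their library preparation or their depth without telling which.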

How the results depend on the processing

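Scaling by total tags, the quasi-Poisson test, the omission of highly filled positions, calls in each brain alone, the letter in the titles, other neighbour distances and, outside the tests between brains, repeated rows counted once per library were chosen after seeing the data. The share of clusters with both brains' tags was 97.46% with repeated rows counted once over all libraries, 99.8% with them counted once per library, 91.5% at a height of 5, 100% at a height of 30, 97.9% with a 10-nt overlap and 66.7% for clusters of height 5 called in brain 2 alone and sought among those of brain 1 (33.0% the other way); leaving out each library gave 97.8 to 99.6%. It cannot be computed without a brain. Clusters of height 100 numbered 0 and 14 with repeated rows counted once over all libraries and per library, 226 with a 10-nt overlap and 149 to 178 with a library left out. The plus share stayed between 42.5 and 43.0% in its alternatives. Clusters that differed between brains numbered 15 with total scaling and 3 to 9 with a library left out. There was 1 without highly filled positions, which takes out 4 of the 6. With repeated rows counted once there were 4, of which 2 were higher and 1 was among the 6. Windows numbered 8 with total scaling, 14 with repeated rows counted once and 16 to 45 with a library left out. Without the count filter, among windows with 20 or more tags, 13 passed. The quasi-Poisson test gave 4 clusters and 42 windows. The letter as a random block (correlation within a letter 0.05 and -0.05) gave 6 clusters and 50 windows, and its 2 libraries summed, which leaves 2 values per brain, 3 and 22. The replicate number as a block gave 5 clusters and 40 windows; the numbers share no pairing, since deviations of same-numbered libraries correlated between -0.020 and 0.006. Of 184 alternatives for the 12 named features, 126 kept the call and 58 lost it, with no change of direction. The chromosome 5 cluster and its window, which hold almost the same tags, kept it in the 16 and 15 run. With repeated rows counted once, 7 of the 12 (2 clusters and 5 windows, those on chromosome 5 among them) fell below the filter and were not tested. The window at 36260001 on chromosome 2 lost the call in 12 of 15, those at 160450001 on chromosome 1 and 17610001 on chromosome 4 in 9 and 8 of 15, and the chromosome 1 window with 84 and 2 tags in 7 of 13. The cause was not tested. The share of clusters with a same-strand neighbour was 15.6% at 500 nt and 35.6% at 5000 nt. The planned second count tool was not run, and median-of-ratios scaling, with 6 clusters and 44 windows, stood in for it. The alternatives of the 4 results not analysed were not run.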

Other observations

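Tag ends recurred between brains more sharply at the 5′ side than at the 3′ side. Distinct 3′ ends of brain 2 coincided with those of brain 1 at 150119 of 935573 positions, 2.45 times as often as at a shift of 1 nt, against 4.80 times for 5′ ends. Tag lengths of 27 to 30 nt put the 3′ ends of tags with one 5′ end at different positions. This can lower the 3′ ratio by itself, so the contrast cannot be read as a property of the RNA fragments. Across 34816 strand-specific windows with 20 or more tags, log2 tags of the brains correlated at 0.69 (Pearson) and 0.57 (Spearman); windows are not independent replicates. Dispersion of counts between library pairs was taken as chi-square per degree of freedom over windows. It was 1.13 to 1.27 within brain 1, 1.16 to 1.55 within brain 2 and 1.35 to 1.65 between brains. Without library 4 of brain 2 it was 1.16 to 1.29 within brain 2 and 1.35 to 1.45 between brains. That library gave 1.46 to 1.55 within its own brain. No pair agreed within sampling noise, which here takes each tag as an independent molecule, although some tags may be repeated reads. Around the chromosome 1 window with 84 and 2 tags, the window that follows it held 27 tags in brain 1 and 11 in brain 2, and the 86 tags of the window itself lay at 59 distinct positions.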
